A study of Mus musculus with 4 samples.

How the data were processed

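The series measured microRNAs (miRNAs, short RNAs that repress messenger RNAs) in total RNA from 2 normal mouse livers and 2 mouse liver tumours. Per the labels' protocols, female mice with a floxed Nf2 gene were given PBS or a liver-directed adeno-associated virus carrying Cre recombinase, which deletes Nf2 in hepatocytes. Nf2 encodes merlin, a tumour suppressor upstream of the Hippo pathway and its effector YAP. Livers were inspected 50 weeks later and tumours were dissected; the protocols give 3 mice without saying how they divide. The labels do not say that the normal samples came from the PBS mice, nor that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Within each group the counts differed by more than sampling noise (chi-square per probe 3.13 between the normal livers over 346 probes and 34.0 between the tumours over 408 probes, for probes with a summed count of at least 20), and the samples were counted separately.

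Per the labels, the assay was the nCounter miRNA Expression Assay of NanoString, which ligates a tag to each miRNA, hybridises colour-coded probes and counts them one by one. The deposited values are signal values, probe counts that the authors multiplied by a factor; the software and what set the factor are not given in the sources used here. The table held 618 probes. Of these, 566 were for mouse miRNAs (9 of them naming several miRNAs), 33 for miRNAs of mouse herpesviruses, 4 for messenger RNAs, 6 were negative controls, 6 were positive controls and 3 were for plant or worm miRNAs. The values of the miRNA, viral and messenger RNA probes were whole counts times 1 factor per sample (100% of values whole in every sample, within 0.1 count), so the probe counts could be recovered. The factors were 2.086 and 2.296 for the normal livers and 0.395 and 0.9051 for the tumours. Control and plant or worm probes were left unscaled. The factors set the geometric mean of the 100 miRNAs with the highest mean count equal in all 4 samples, with a coefficient of variation of 2e-04 percent. The overall level of these miRNAs therefore cannot differ between samples in the deposited values.

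Recovered counts over the scaled probes totalled 70204 and 63744 in the normal livers and 247020 and 129422 in the tumours. A miRNA was called detected in a sample where its recovered count exceeded the mean plus 2 SD of that sample's negative controls (18.3 and 11.2 counts in the normal livers, 17.6 and 14.9 in the tumours). Where a miRNA was detected in neither sample of a group, its fold is given as a bound. The bound is the geometric mean of the other group over that of the higher, per sample, of the scaled detection threshold and the miRNA's own value. For a fall the bound still counts scaled background in the normal livers as signal, so it is not a lower limit. List medians are also given with such miRNAs at their bound, or at 0 where the bound gives no fold, a choice made after seeing the data.

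The main test was limma (lmFit and eBayes, two-sided) on log2(value + 1), with Benjamini-Hochberg adjustment over the miRNAs kept and a threshold of 0.05. Differences are tumour minus normal on that scale. The added 1 shrinks the differences of low miRNAs. Scaled background was higher in the normal livers and can pull the differences of low miRNAs towards a fall, so their falls are not conservative. A miRNA was kept where its mean log2 value exceeded the mean plus 2 SD of the scaled negative controls, 3.925, and 276 were kept. The median difference over kept miRNAs was tested with an exact permutation test of the 4 per-sample medians. Sets of miRNAs were tested with camera (preset correlation 0.01) where at least 3 members were kept. Camera compares a set with the other kept miRNAs, whose differences centred below 0, so a set can be called upward without rising itself. In all, 20 lists were fixed, and 17 could be tested. Named miRNAs were the 12 largest called rises and the 12 largest called falls with both tumours beyond both normal livers, up to 4 members per list with the largest differences, and the 10 with the highest mean in normal liver. Those tests, filters, lists, the rule for named miRNAs and a first set of other settings were chosen before the data were examined. A second ranking, over the miRNAs detected in all 4 samples, was added after seeing the data.

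That first set of other settings held other scalings (equal medians, quantile normalization, equal totals, equal geometric mean of the 100 miRNAs with the highest mean value), other filters, pseudocounts of 0.5, 10 and 30, each sample left out in turn, the replicate number as a block, other variance models and thresholds, and other set tests. Settings added after seeing the data were edgeR's quasi-likelihood test on the recovered counts, a scaling to the positive controls, filters based on detection or on viral probes, and subtraction or flooring of background. For miR-802, detected in 1 tumour, a fold with the other tumour at its detection threshold was also added. The limma test alone was tried on simulated counts for the 276 kept probes, 60 of them changed. The filter and the scaling were not repeated, no background was added, and 1 dispersion (0.038) served for both groups. The real tumours differed more from each other than the normal livers did, so the rates that follow may not hold for them. Over 20 runs limma recovered 33.2% of 2-fold and 92.2% of 4-fold changes, with a mean of 2.1 false calls per run. Genomic neighbours were taken from a RefSeq table of assembly GRCm38.p6, in which 463 of the 566 mouse probes matched exactly 1 locus. R 4.3.3, limma 3.58.1 and edgeR 4.0.16 were used. Precision is limited by 2 samples per group and, for low miRNAs, by probe background.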

Results

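Levels of miRNAs were measured by digital probe counting in 2 normal mouse livers and 2 liver tumours from a model in which Cre recombinase deleted Nf2 in hepatocytes. The comparison asked which miRNAs differ between normal liver tissue and tumours induced by loss of Nf2. Recovered probe counts totalled 70204 and 63744 in the normal livers and 247020 and 129422 in the tumours. Of 566 mouse miRNA probes, 163 and 272 were above the negative controls in the normal livers, 311 and 209 in the tumours, 136 in all 4 samples and 214 in none. The liver-specific miR-122 took 17.2% and 20.4% of miRNA counts in the normal livers and 13.2% and 14.6% in the tumours. The probe for miR-720, now regarded as a transfer RNA fragment, took 18.6% and 16.6% in the normal livers and 9.11% and 18.3% in the tumours.

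The miR-200 family, which keeps cells epithelial and in liver is typical of bile duct cells, held the largest rises in the tumours. MiR-200a rose from 56.6 ± 5.42 to 479 ± 75.5 scaled counts (SD, n = 2 per group), a log2 difference of 3.05 (SE 0.27, limma adjusted p = 0.0017) or 8.29-fold. MiR-200b rose from 88.2 ± 21.4 to 528 ± 2.60, a log2 difference of 2.59 (SE 0.28, adjusted p = 0.00274). MiR-429, encoded beside them, was not detected in either normal liver (7 and 9 counts) and reached 254 ± 49.4 in the tumours, at least 8.03-fold higher (adjusted p = 0.0014). The fourth kept member, miR-200c, was detected in neither normal liver (17 and 9 counts) and in 1 of the tumours (33 and 9 counts), so no size of difference is given. Limma called its scaled value lower (adjusted p = 0.0238), a call that ended without normal liver replicate 1, normal liver replicate 2 or liver tumour replicate 2, and its direction flipped under quantile normalization. The fifth member, miR-141, was detected in 1 tumour only (11 and 6 counts in the normal livers, 28 and 10 in the tumours) and was not kept. Of 4 kept members, 3 rose and 1, miR-200c, was called lower, also when adjusted over the list alone. The 3 that rose are the ones encoded side by side. The median log2 difference was 2.82, or 2.80 with miR-429 at its bound and miR-200c at 0. Camera called the list upward (adjusted p = 0.000439). The call was lost with an estimated correlation (adjusted p = 0.435 with an estimated correlation). The same 3 members rose under each of the 7 scalings, edgeR on recovered counts included. The 6 other than the deposited one all raised the tumours relative to the normal livers, which favours rises. With each sample left out in turn the median of the list was 2.74 to 2.90.

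**Figure D1:**
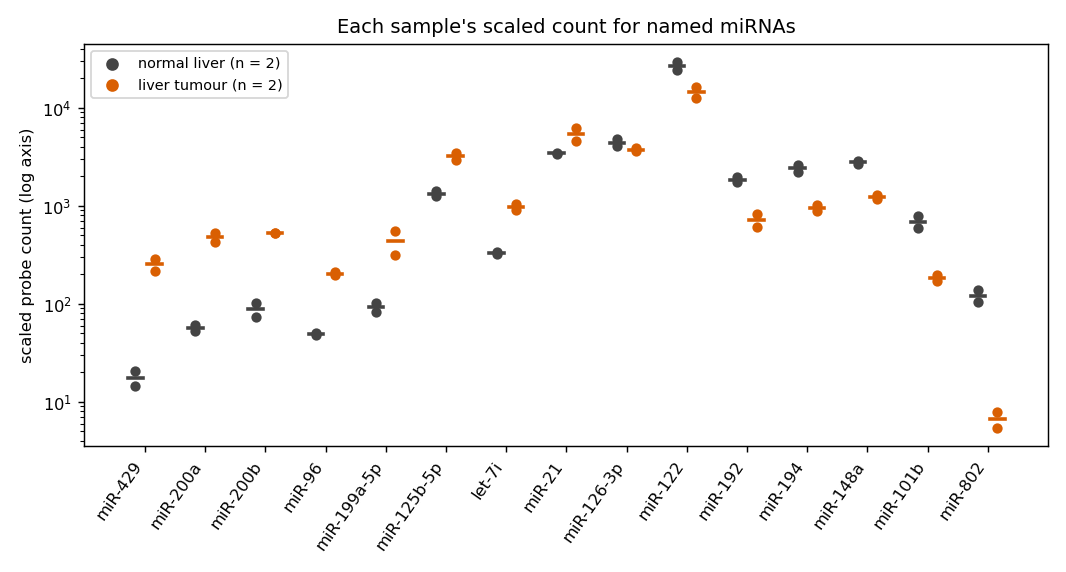
Scaled probe count (vertical log axis) of 15 named miRNAs in each of the 2 normal livers (grey points) and 2 liver tumours (orange points), with short lines at group means. Both tumours lie above both normal livers for miR-429, miR-200a and miR-200b, while miR-122 lies at 26814 on average in normal liver and 14442 in tumours, a difference whose direction turned under scaling to the positive controls.

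Other rises joined the miR-200 family. MiR-96, of the miR-183 cluster that is often raised in carcinomas, rose from 49.1 ± 1.29 to 204 ± 12.4 (4.08-fold, adjusted p = 0.00274). Its cluster neighbour miR-183 was detected in neither normal liver and was at least 1.15-fold higher in the tumours (adjusted p = 0.00964). The other member of that cluster, miR-182, was detected in no sample (4 and 4 counts in the normal livers, 14 and 11 in the tumours) and was not kept. MiR-125a-5p rose from 218 ± 6.8 to 768 ± 81.4 (3.5-fold, adjusted p = 0.00338). MiR-181a, known from lymphocyte development and from liver progenitor-like tumours, rose from 99.3 ± 4.07 to 317 ± 4.48 (3.17-fold, adjusted p = 0.00339). MiR-222, which represses the cell cycle inhibitor p27, was detected in neither normal liver and was at least 2.43-fold higher in the tumours (adjusted p = 0.00478). The 6 scalings other than the deposited one all raised the tumours relative to the normal livers. The median over kept miRNAs was -0.75 to 0.091 under them, against -0.90 as deposited. They therefore favour rises, and a rise kept under them is a weak test of scaling. Of the 22 miRNAs called higher, 13 kept the call under each of the 7 scalings, and all 22 kept it under the 6 other than quantile normalization. MiR-200a, miR-200b, miR-429, miR-96, miR-125a-5p, miR-181a and let-7i, 7 in all, kept it without each sample in turn. MiR-183 lost its call without either normal liver, and miR-222 without normal liver replicate 2.

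Hepatocyte-enriched miRNAs were lower in the tumours in the deposited scaling. Of 13 kept members 11 fell and 0 rose, with the same counts when adjusted over the list alone and a median log2 difference of -1.09. MiR-122 averaged 26814 ± 3235 in normal liver and 14442 ± 2750 in tumours, a log2 difference of -0.90 (SE 0.28, adjusted p = 0.0348). MiR-192 fell from 1854 ± 160 to 718 ± 146 (log2 difference -1.38, adjusted p = 0.00799), and miR-194, made with it, fell from 2429 ± 292 to 954 ± 86.8 (-1.35, adjusted p = 0.00726). MiR-101b fell from 689 ± 137 to 183 ± 18.5 (-1.89, adjusted p = 0.00339). MiR-802, a liver-enriched regulator of glucose metabolism, fell from 121 ± 23.7 to 6.67 ± 1.75 scaled counts (-4.00, adjusted p = 0.0014). It was above the negative controls in both normal livers (50 and 60 counts) and in 1 tumour (20 counts, against 6 in the other, with thresholds of 17.6 and 14.9), so the size of the fall rests on tumour values near background. With the tumour that lacked detection set at its threshold, it was 11.6-fold lower (log2 difference -3.54). MiR-802 kept its call under each of the 7 scalings and without each sample in turn. For the rest of the list the fall depended on the scaling. With the positive controls set equal, 1 of 13 fell, 1 rose and the median was -0.068, with miR-122 at 0.12. EdgeR on recovered counts called 2 lower and 1 higher. The list fell by the self-contained fry test (adjusted p = 0.00707). Fry also called the testis and neuronal lists, included as a measure of background, downward (adjusted p = 0.025 for each). Camera, which compares the hepatocyte-enriched list with the other kept miRNAs, did not call it (adjusted p = 0.0955, and 0.443 with an estimated correlation). Without normal liver replicate 1, 3 members were called lower, 2 without normal liver replicate 2 and 7 without liver tumour replicate 1. MiR-122, miR-192 and miR-194 lost their calls without either normal liver, and miR-122 also without liver tumour replicate 1.

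Of the mesenchymal, leukocyte, endothelial and erythroid lists, which were not tested against each other, the mesenchymal one held the most rises called by limma in the deposited scaling. Of 9 kept mesenchymal and stellate cell miRNAs 3 rose and 0 fell, also when adjusted over the list alone. EdgeR called 8 higher (median 1.09), and limma 6 with equal medians (1.06) and 4 with the positive controls set equal (1.26). MiR-199a-5p, abundant in hepatic stellate cells, went from 93.4 ± 14.1 to 435 ± 173 (4.46-fold, adjusted p = 0.0036), miR-199a-3p from 211 ± 11.96 to 682 ± 283 (adjusted p = 0.00964), and miR-125b-5p from 1329 ± 109 to 3187 ± 345 (adjusted p = 0.00853). The median of the list was 0.24, or 0.26 with the 1 member not detected in a group at its bound or 0, and camera called it upward (adjusted p = 0.000351), a call lost with an estimated correlation (adjusted p = 0.443 with an estimated correlation). Smooth muscle miR-143 (log2 difference 0.12, adjusted p = 0.786) and miR-145 (0.14, adjusted p = 0.723) were not called by limma, whereas edgeR called both higher (1.06, adjusted p = 0.0219, and 1.01, adjusted p = 0.0127). Without normal liver replicate 1 the list held 1 rise and without normal liver replicate 2 limma called 0 (3 at an unadjusted p under 0.05); both miR-199a arms lost their calls in each case and miR-125b-5p without normal liver replicate 2. Of 9 leukocyte miRNAs 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0737, and 0.443 with an estimated correlation). The rise was miR-181a. EdgeR called 5 higher and 1 lower, and limma 4 higher with equal medians, with equal totals and with the positive controls set equal. MiR-142-3p, the arm opposite miR-142-5p, was not called by limma (log2 difference 0.083, adjusted p = 0.867). It averaged 200 ± 55.3 in normal liver and 217 ± 88.98 in tumours, and edgeR called it higher (0.999, adjusted p = 0.0344). MiR-155, induced in activated leukocytes, fell from 694 ± 152 to 251 ± 68.3 (adjusted p = 0.00964), and miR-142-5p from 113 ± 24.7 to 23.4 ± 9.11 (adjusted p = 0.00339). Both lost their calls without normal liver replicate 2 and with the positive controls set equal, and without liver tumour replicate 2 the list held 3 rises. Endothelial miR-126-3p averaged 4423 ± 508 in normal liver and 3743 ± 168 in tumours (log2 difference -0.24, adjusted p = 0.461), and turned to 0.79 with the positive controls set equal, 0.58 with equal medians, 0.23 with equal totals and 0.61 in edgeR, which called it higher (adjusted p = 0.0399). MiR-126-5p was called lower (-0.93, adjusted p = 0.0227), a call lost without any 1 of the 4 samples and turned to 0.087 with the positive controls set equal. Of 3 erythroid miRNAs limma called 0, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 against 3 called higher by edgeR (median 1.24) and 2 by limma with equal medians or the positive controls set equal. MiR-451, the most abundant of them, had a log2 difference of 0.47 (adjusted p = 0.167).

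Among miRNA families, let-7i had the largest difference of the let-7 family, whose members act against growth-promoting genes such as Lin28 and Ras. It rose from 330 ± 10.1 to 984 ± 96.2 (log2 difference 1.57, adjusted p = 0.0036). Of 9 kept let-7 members 2 rose and 0 fell, or 1 rose when adjusted over the list alone, with a median of 0.28. EdgeR called 8 of the 9 higher (median 1.15), and limma 6 with equal medians (1.09) and 5 with the positive controls set equal (1.30). The other rise in the deposited scaling was let-7e (0.72, adjusted p = 0.047), whose call was lost without any 1 of the 4 samples. Camera called the family upward (adjusted p = 0.00511), though not with an estimated correlation (adjusted p = 0.435 with an estimated correlation). Of 7 members of the miR-17-92 and paralogous clusters, which promote proliferation, 2 rose, or 0 when adjusted over the list alone. These were miR-25 (1.01, adjusted p = 0.0196) and miR-106b (0.82, adjusted p = 0.0405). Camera called this list upward at a median of 0.06 (adjusted p = 0.0396; adjusted p = 0.443 with an estimated correlation). Without normal liver replicate 1 or normal liver replicate 2 limma called 0 members (1 and 0 at an unadjusted p under 0.05, with 6 called higher by edgeR over all samples), and without either tumour 1. Of 3 miR-29 members, which repress collagens, 1 fell, or 3 when adjusted over the list alone, with a median of -0.74 that turned to 0.28 with the positive controls set equal, 0.07 with equal medians and 0.14 in edgeR. Without liver tumour replicate 1 limma called 2 members lower and without any other sample 0 (0 at an unadjusted p under 0.05; edgeR called 0 over all samples). Of 5 miR-30 members 1 fell, also when adjusted over the list alone. It was miR-30c, from 325 ± 46.8 to 95.5 ± 3.20 (adjusted p = 0.00339), a call that ended with the positive controls set equal (-0.73, adjusted p = 0.276), and the median of -0.81 turned to 0.21 with the positive controls set equal and 0.087 in edgeR, and lay at 0.00062 with equal medians. Without liver tumour replicate 1, 3 members were called lower. Within the miR-15/16 family miR-15b rose (0.90, adjusted p = 0.0239) and miR-15a fell (-0.85, adjusted p = 0.029) among 6 members, also when adjusted over the list alone. EdgeR called 4 of the miR-15/16 family higher and 0 lower (5 at an unadjusted p under 0.05). The fall of miR-15a was lost without any 1 of the 4 samples, and turned to 0.18 with the positive controls set equal and to 0.012 in edgeR; the rise of miR-15b was lost without normal liver replicate 1, normal liver replicate 2 or liver tumour replicate 1. Of 5 members of the miR-23/27/24 clusters, 1 rose, miR-23a (1.02, adjusted p = 0.0204), also when adjusted over the list alone, and its call was lost in those same 3 cases, while edgeR called 4 higher. Camera called none of these last 4 families (adjusted p = 0.638, 0.817, 0.0708 and 0.0879), and the miR-23/27/24 median of -0.09 went against its upward direction in camera and turned above 0 under the other 6 scalings, to 0.93 at most.

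Of the 10 miRNAs with the highest mean in normal liver, 3 were called, all lower, namely miR-122, miR-22 and miR-148a. MiR-22, abundant in many tissues, fell from 12873 ± 439 to 5412 ± 1416 (log2 difference -1.27, adjusted p = 0.0115), and miR-148a from 2766 ± 166 to 1225 ± 70.4 (-1.17, adjusted p = 0.00964). Both lost their calls without either normal liver and with the positive controls set equal, where their differences were -0.25 and -0.15. The other 7 were not called by limma in the deposited scaling, whereas edgeR called let-7c, miR-21, let-7g and miR-126-3p higher (adjusted p = 0.00153, 0.00147, 0.0274 and 0.0399). Limma called let-7c and miR-21 higher with the positive controls set equal (adjusted p = 0.0157 and 0.00842). Their log2 differences were -0.91 for miR-720, -0.74 for miR-29a, -0.50 for let-7a, -0.24 for let-7g, -0.24 for miR-126-3p, 0.52 for let-7c and 0.64 for miR-21. The 5 negative differences turned positive with the positive controls set equal and in edgeR.

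Among 14 miRNAs reported as raised in liver cancer, 6 rose and 2 fell, also when adjusted over the list alone, with a median of 0.56. EdgeR called 9 higher and 0 lower (median 1.43). Camera called the list upward (adjusted p = 0.000121), though not with an estimated correlation (adjusted p = 0.435 with an estimated correlation). With miR-222 and miR-183 at their bounds the median was 0.44. The rises were those of miR-96, miR-222, miR-183, miR-25, miR-106b and miR-34a, and the falls were those of miR-155 and miR-135a. Without normal liver replicate 1 the list held 2 rises, and without normal liver replicate 2 it held 1 rise and 0 falls in limma (5 members at an unadjusted p under 0.05; edgeR called 0 lower over all samples). MiR-21, the most abundant member and a frequent oncogenic miRNA, averaged 3443 ± 60.9 in normal liver and 5427 ± 1193 in tumours and did not pass the test (log2 difference 0.64, adjusted p = 0.0931), whereas edgeR called it higher (adjusted p = 0.00147). Among 19 miRNAs reported as lowered in liver cancer, 4 rose and 7 fell, also when adjusted over the list alone. The counts turned to 8 higher and 2 lower in edgeR and with equal medians, and to 6 higher and 0 lower in limma with the positive controls set equal (9 at an unadjusted p under 0.05). The 4 rises, which opposed the name of the list, were both miR-199a arms, miR-125a-5p and miR-125b-5p. Its median was -0.56, turning to 0.46 with the positive controls set equal, 0.25 with equal medians and 0.28 in edgeR, while camera placed it upward without calling it (adjusted p = 0.0955). Without normal liver replicate 1 it held 2 rises and 2 falls, and without normal liver replicate 2 it held 1 rise and 3 falls.

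The set tests varied with the setting. Camera called 6 of 17 lists. After quantile normalization the calls of the let-7 family, the miR-17-92 clusters, the Dlk1-Dio3 cluster and the mesenchymal list were lost (adjusted p = 0.232, 0.558, 0.283 and 0.0505) and the hepatocyte-enriched list was called downward (adjusted p = 0.00321). With equal medians the miR-15/16 and miR-23/27/24 lists were called upward (adjusted p = 0.0354 for each). With the positive controls set equal the miR-17-92 and Dlk1-Dio3 lists were not called (adjusted p = 0.058 and 0.0626). Among miRNAs detected in all 4 samples, the hepatocyte-enriched list was called downward (adjusted p = 0.0287), and the mesenchymal list and that of miRNAs raised in liver cancer upward (adjusted p = 0.0264 and 0.0287), none of them with an estimated correlation (adjusted p = 0.579 for each). Only 12 lists had enough members for this fit, and the miR-200 family, with 2, was not among them. Without liver tumour replicate 2, camera also called the leukocyte, miR-15/16 and miR-23/27/24 lists and that of miRNAs lowered in liver cancer upward (adjusted p = 0.0247 for each). Without normal liver replicate 1 it called the erythroid list (adjusted p = 0.0369), and without normal liver replicate 2 the miR-15/16 family (adjusted p = 0.0318).

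**Figure D2:**
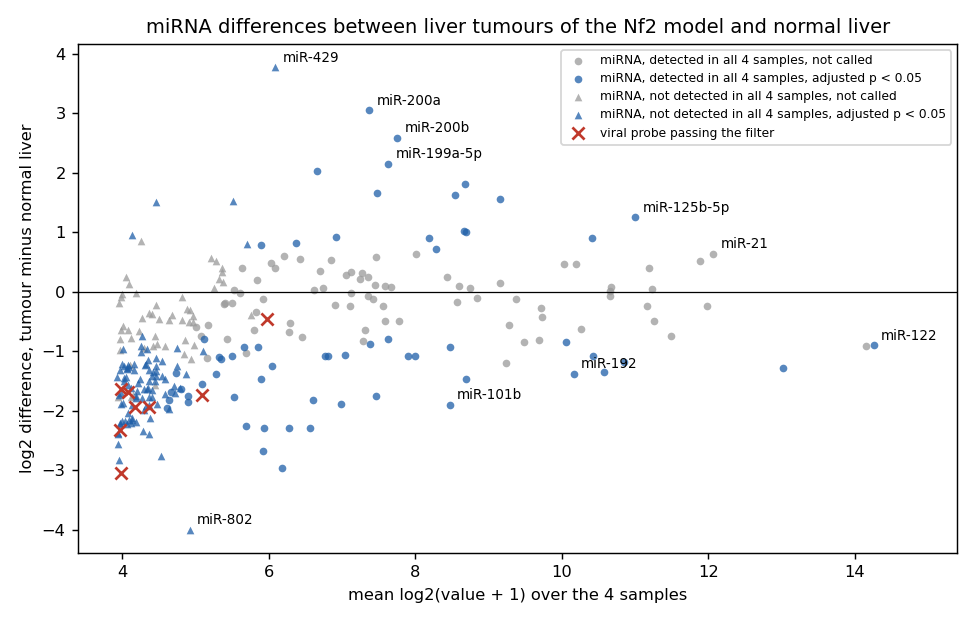
Log2 difference between liver tumours and normal livers (vertical axis, n = 2 per group) against mean log2(value + 1) over the 4 samples (horizontal axis) for 276 kept miRNAs; circles were detected in all 4 samples, triangles were not, and blue marks adjusted p under 0.05 in limma. Crosses mark 8 viral probes that pass the same filter, with a median of -1.83. Most lie among the low miRNAs called lower, while mghv-miR-M1-7-5p lies apart at a mean of 5.98 and a difference of -0.46.

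Of the 129 called falls, 85 were of miRNAs not detected in all 4 samples. MiR-802, miR-714, miR-762 and miR-764-5p, 4 in all, kept the call under each of the 7 scalings, and they also kept it without each sample in turn. MiR-764-5p had 20 and 19 recovered counts in the normal livers and 18 and 9 in the tumours, close to background, which the scalings do not remove. In the Dlk1-Dio3 imprinted cluster, a large group of placental mammal miRNAs, 15 of 21 kept members were called lower and 0 higher, or 17 lower when adjusted over the list alone, with a median of -1.42, or -1.36 with the 3 members not detected in a group at their bounds or 0. Camera called the list downward (adjusted p = 0.0474), though not with an estimated correlation (adjusted p = 0.572 with an estimated correlation), nor without liver tumour replicate 1 (adjusted p = 0.19), and without normal liver replicate 2 only 6 members were called. Only 7 members were detected in all 4 samples, of which 4 were called lower in a fit to such miRNAs, and with the positive controls set equal limma called 0 of 21 (3 at an unadjusted p under 0.05; edgeR called 4 lower). Lists of other tissues, included as a measure of background, gave falls too. Of 7 kept miRNAs from X-linked testis clusters 5 were called lower (median -1.15), of 4 muscle miRNAs 1, of 3 neuronal miRNAs 2, with miR-132 higher, and the 1 kept pluripotent cell miRNA, miR-367, was called lower. No pancreas miRNA was kept, and camera called neither the testis, the muscle nor the neuronal list (adjusted p = 0.229, 0.908 and 0.897). Fry called the testis and neuronal lists downward (adjusted p = 0.025 for each) but not the muscle list (adjusted p = 0.109). Adjusted over the list alone the counts of called members were the same. With the positive controls set equal limma called 0 testis, muscle or pluripotent members, with 0 at an unadjusted p under 0.05 and 0 called by edgeR. MiR-132 lost its call without any 1 of the 4 samples, and miR-367 without normal liver replicate 2. Of the testis list 2 were called lower without normal liver replicate 1, and limma called 0 without normal liver replicate 2 (5 at an unadjusted p under 0.05; edgeR called 0 over all samples). Its median turned to 0.13 after quantile normalization. The muscle list held 2 falls without liver tumour replicate 1 and 0 in limma without normal liver replicate 2 (2 at an unadjusted p under 0.05; edgeR called 0 over all samples). The neuronal list held 1 fall without either normal liver or without liver tumour replicate 1. The fixed rule for large falls also took miR-762, miR-767, miR-1893, miR-714, miR-882, miR-710, miR-879, miR-1903, miR-764-5p, miR-203 and miR-107. MiR-762 was detected in all 4 samples, with 83 and 102 recovered counts in the normal livers and 82 and 21 in the tumours, and its log2 difference of -2.97 was -1.96 with the positive controls set equal (adjusted p = 0.00165) and -2.06 in edgeR (adjusted p = 0.00147). MiR-203, with 86 and 71 counts against 96 and 34, lost its call with the positive controls set equal (adjusted p = 0.0515). MiR-882 (23 and 12 counts in the normal livers, 16 and 5 in the tumours) and miR-1903 (20 and 12 against 10 and 9) were detected in neither tumour. Their bounds, 3.76-fold and 3.5-fold lower, take normal values near the detection thresholds as signal and rest largely on the factors. They are therefore not lower limits of a fall. MiR-1893 lost its call without either normal liver, and miR-1903 without normal liver replicate 1.

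Background itself differed between the groups once scaled. The mean of the 6 negative controls was 8.83 and 7.67 counts in the normal livers and 7.5 and 7.67 in the tumours. Multiplied by the factors of the samples, it became 18.4 and 17.6 in the normal livers and 2.96 and 6.94 in the tumours. The 33 viral miRNA probes had medians of 22.9 and 20.7 scaled counts in the normal livers and 5.93 and 5.43 in the tumours.

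**Figure D3:**
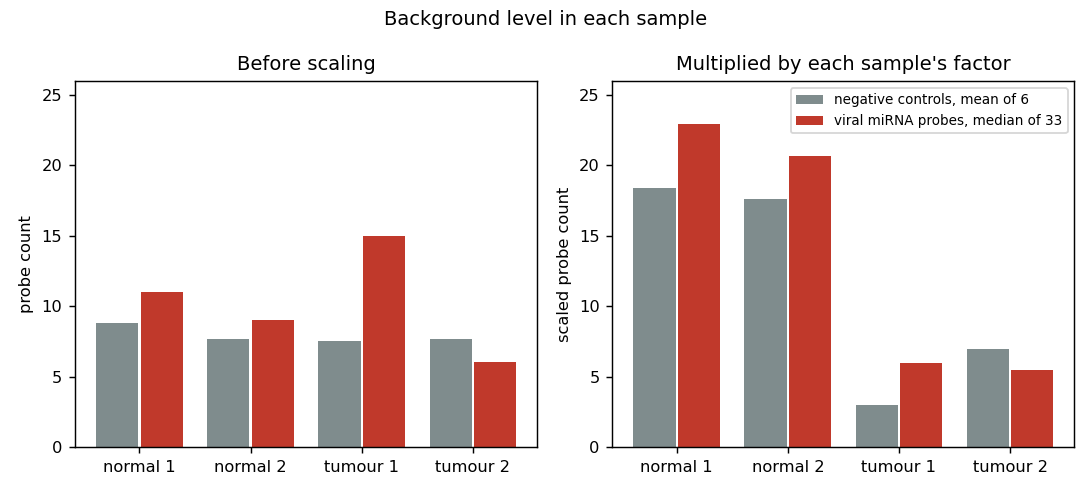
Mean of the 6 negative controls (grey bars) and median of the 33 viral miRNA probes (red bars) in each of the 4 samples, as probe counts (left) and multiplied by each sample's factor (right). Negative controls lie between 7.5 and 8.83 counts before scaling, and at 18.4 and 17.6 in the normal livers against 2.96 and 6.94 in the tumours after it.

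Over all 276 kept miRNAs, limma called 22 higher and 129 lower in the tumours, and 76.5% had a lower mean. The median log2 difference was -0.90. Per-sample medians were 5.55 and 5.55 in the normal livers and 4.8 and 4.72 in the tumours, and the exact two-sided permutation test gave p = 0.333, the smallest that 2 samples against 2 allow. Detection divided the calls. Of the 22 miRNAs called higher 17 were detected in all 4 samples, against 44 of the 129 called lower. Among the 136 miRNAs detected in all 4 samples, a fit added after seeing the data called 17 higher and 50 lower, with a median of -0.31. With the positive controls set equal these 136 gave 51 higher and 6 lower, with a median of 0.71. The split of calls moved with the scaling, to 59 higher and 50 lower with equal medians, 18 and 11 after quantile normalization, 34 and 74 with equal totals, 44 and 10 with the positive controls set equal, and 71 and 39 in edgeR on recovered counts. The median moved with it, to -0.11, -0.023, -0.45, 0.091 and -0.033. The edgeR calls included all 22 higher and 39 of the 129 lower, and none was opposite. Leaving out normal liver replicate 1 gave 11 higher and 76 lower, and normal liver replicate 2 gave 7 and 47. In the detected set, the limma calls depended on which group kept a lone sample. Few or none remained without either normal liver, where the spread comes from the tumours alone. Without either tumour, where it comes from the normal livers alone, the calls were no fewer than with all samples.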

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

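The tests of background for called falls, of total level, of cell share and of scaling were chosen only after the results were seen. The messenger RNA probes on the panel were not used in the comparison, and the probe for Rpl19, a ribosomal protein gene, stood higher in both tumours (434 and 998 scaled counts) than in both normal livers (365 and 413), a log2 difference of 0.76. In the same scaled counts Gapdh was lower in both tumours (137 and 192 against 307 and 289), while Actb (635 and 1494 against 742 and 762) and B2m (1419 and 2151 against 1823 and 1603) were lower in 1 tumour and higher in the other. These directions hold for the deposited scaling only. The messenger RNA probes were not compared under the other scalings, where a direction may turn.

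Called falls outnumbered called rises by 129 to 22. For the 17 falls with counts above every viral probe in each sample, miR-122, miR-192 and miR-194 among them, background is argued against, since subtracting the negative control mean left all 17 lower with a median of -1.05. For the 85 falls not detected in all 4 samples (median -1.62), like background counts multiplied by larger factors in the normal livers are a candidate explanation, since the 8 viral probes passing the same filter had a median of -1.83. A simulation of equal signal plus equal background gave a median of 1.5 falls per run (0 to 43 over 20 runs). It cannot decide this, because it gave every probe the same mean background. Viral probes reached 30 and 37 counts in the normal livers and 159 and 49 in the tumours. For the other 27, with a median of -1.69, subtraction left all 27 lower with a median of -1.61. This argues against background of the size of the negative control mean as the whole cause. Higher background, as of the viral probes, and a true fall cannot be told apart, since the median of -1.69 lies within the viral interquartile range (-2.03 to -1.68). A lower total miRNA level in the tumours cannot be told apart from the scaling either, because the 100 leading miRNAs stood 1.02 higher on the log2 scale per positive control in the tumours but the RNA input per lane is not given in the sources used here.

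Hepatocyte-enriched miRNAs were lower (median -1.09) and the miR-200 family higher (median 2.82) in the tumours. A lower share of hepatocytes with the other cell types in unchanged proportions would raise the miRNAs of those types alike. That form is argued against by the miR-200 family lying 3.06 above endothelial miR-126-3p. A lower share of hepatocytes with a gain of only some cell types is not decided by this value and stays open. The scaling stays open for the hepatocyte-enriched list, whose median was -0.068 with the positive controls set equal. For the miR-200 family the lowest median over the 7 scalings was 2.82, the deposited one. That value cannot argue against the scaling. The 6 others all placed the median over kept miRNAs above the deposited -0.90, and so favoured rises. The gap between these lists was 3.91 as deposited and 3.90 to 4.12 under the others. A factor per sample leaves such a gap nearly unchanged, so it cannot account for it. A gain of bile duct-like cells and altered miRNA levels within Nf2-deleted tumour cells, the difference the design names, also stay open and were not tested.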

How the results depend on the processing

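Scaling to the positive controls, edgeR on recovered counts, the filters on detection or viral probes, background subtraction, the common floor and detection thresholds in place of undetected values were chosen only after the data were seen; the other settings were chosen before. Called miRNAs (151, with 22 higher and 129 lower) numbered 109 with equal medians (59 higher, 50 lower), 29 after quantile normalization (18 higher, 11 lower), 108 with equal totals (34 higher, 74 lower), 54 with the positive controls set equal (44 higher, 10 lower) and 110 in edgeR (71 higher, 39 lower). Filters gave 292 calls with no filter (276 lower), 66 with the lowest sample above background and 66 for the 150 highest miRNAs (46 lower in each), 96 for miRNAs detected in both samples of a group (74 lower), 67 for those detected in all 4 samples (50 lower) and 63 with viral probes as background (43 lower). Subtracting the negative control mean in the set detected in all 4 samples gave 53 calls (33 lower) and the common floor 53 (34 lower). A log2 difference of at least 1 left 14 higher. Leaving out 1 sample gave 54 to 145 calls, 7 to 18 higher and 47 to 127 lower, lowest without normal liver replicate 2; a lone sample of a group is then assumed to vary like the other group. The median difference (-0.90) was -0.11 with equal medians, -0.023 after quantile normalization, -0.45 with equal totals, -0.75 with the 100 highest by value set equal, 0.091 with the positive controls set equal and -0.033 in edgeR. It was -1.20 with no filter, -0.28 with the lowest sample above background, -0.24 for the 150 highest, -0.50 detected in a group, -0.31 detected in all 4 samples, -0.18 with viral probes as background, -0.19 after subtraction and -0.14 with the common floor. Pseudocounts of 10 and 30 gave -0.70 and -0.47, the mean in place of the median -0.75, and leaving out 1 sample -0.93 to -0.78. Of 17 lists, camera called 6, against 3 after quantile normalization, 11 of 19 with no filter, 3 of the 12 testable for miRNAs detected in all 4 samples, 3 of those 12 after subtraction, 0 with an estimated correlation (1 at an unadjusted p under 0.05; 7 by fry) and 5 to 10 with 1 sample left out. Among the named miRNAs called in the deposited scaling, some turned upward after quantile normalization (miR-200c 0.043, miR-499 0.21, miR-219 0.50, miR-743a 0.13, miR-470 0.17). Others did so with the positive controls set equal (miR-126-5p 0.087, miR-15a 0.18, miR-219 0.056, miR-122 0.12) and in edgeR (miR-15a 0.012). Called falls that were not named were left out of this list. Quantile normalization left 33 further named miRNAs below the threshold, the positive controls 28 and edgeR 19. The smaller sets tested and, for leave-outs, the fewer samples account for part of the lower counts; the cause of the other shifts was not tested. Other pseudocounts, variance models and an adjusted p under 0.10 kept the counts within 1.5 times. The replicate numbers do not pair the samples, whose deviations correlated at 0.04 over 2 pairs; the replicate block gave 162 calls (19 higher, 143 lower). The alternatives set down for raw counts as deposited (DESeq2) were not run, since the values are scaled. Background limits what can be read from miRNAs under about 38.2 scaled counts, the highest scaled detection threshold. It may also limit some above it, since viral probes reached 30 and 37 counts before scaling in the normal livers.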

Other observations

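The test of neighbouring genes was set down before its result was seen, and its repeat without the miR-200 pair was chosen only afterwards, as were the miRNAs named in the next sentences. Of the cluster of miR-99b, let-7e and miR-125a, which was not tested as a group, 3 miRNAs were called higher and 1 lower. MiR-99b, from a family that restrains mTOR, went from 86.4 ± 1.24 to 166 ± 21.3 (log2 difference 0.93, limma adjusted p = 0.0228), let-7e was higher by 0.72 and miR-125a-5p by 1.81. MiR-99b lost its call without normal liver replicate 1, normal liver replicate 2 or liver tumour replicate 1, and let-7e without any 1 of the 4 samples. The opposite arm of the last hairpin, miR-125a-3p, was called lower, from 134 ± 5.98 to 27.4 ± 9.3 (adjusted p = 0.00338), with recovered counts of 62 and 60 in the normal livers and 86 and 23 in the tumours, and lost that call with the positive controls set equal. Both arms of miR-199a rose, and both lost the call without either normal liver. MiR-205, typical of squamous and basal epithelium, was called lower, from 245 ± 40.6 to 66.2 ± 16.5 (adjusted p = 0.00359), with 131 and 94 recovered counts in the normal livers and 138 and 86 in the tumours, and lost that call with the positive controls set equal.

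If miRNAs of 1 genomic cluster, which often share a primary transcript, change together, their log2 differences should vary less within clusters than among random assignments. Among miRNAs detected in all 4 samples, 25 at 1 locus each lay in 11 clusters of neighbours within 10000 bp. The mean variance within clusters was 0.304, against a median of 1.24 over 10000 random assignments (permutation p = 0.00090). Without miR-200a and miR-200b, the pair with the largest rises, it was 0.324 against 0.632 (permutation p = 0.035). Among kept miRNAs not detected in all 4 samples, 29 in 7 clusters gave 0.43 against 0.775 (permutation p = 0.0527), which did not pass 0.05. Shared transcription is a candidate explanation for the likeness, and like probe behaviour of neighbours was not tested. In the deposited scaling 4 of the clusters as tested held differences of opposite sign. They were miR-421 (-1.76) beside miR-374 (0.07), miR-23a (1.02) beside miR-27a (-0.12), miR-30b (-0.81) beside miR-30d (0.10), and miR-144 (-0.17) beside miR-451 (0.47). The arms of miR-125a, neighbour of miR-99b and let-7e, were not among the 25 miRNAs tested. Their differences were also of opposite sign (1.81 for miR-125a-5p, -2.28 for miR-125a-3p), and the test did not cover them.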
